A study of Homo sapiens with 6 samples.

How the data were processed

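RNA from 6 samples of KG1α cells, 3 with a RELA hairpin and 3 with a control hairpin, was measured on single-colour (Cy3) Agilent arrays. Per the labels' protocols, ribosomal RNA was removed and RNA was labelled by random priming along the transcripts. Images were quantified with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. Per the file headers, the arrays are a custom design (number 045997, build hg19), read with protocol GE1_1100_Jul11 in 1 scan. The 6 arrays share that scan and have different positions in it, so they were taken as 1 slide.

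The deposited array files hold intensity per spot. The processed signal is an intensity from which Feature Extraction had removed background within each array, with no scaling between arrays, per the file headers. The median spot and background signals are intensities without correction. Flags of 0 or 1 mark spots that are well above background, saturated or outliers. The deposited table of the series holds log2 values, whose processing by the authors is not given in the sources used here. Each column of that table correlated at 1 with a quantile normalization of log2 processed signals of the same array (median absolute difference at most 0.00015). This settles scale and direction, and every column's median was 5.74.

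Each array has 61184 spots. Of these, 58945 are vendor probes with 1 spot each, and 20 probes have 10 spots each and a RefSeq accession. All 20 accessions matched a gene symbol in a RefSeq gene table of assembly GRCh38.p14, with versions removed on both sides. Since the array build differs from that assembly, no coordinates are given. The vendor probes have no gene in the files used here, so every test over many features was made on probes, and no gene was named from a probe identifier.

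The processed signal was taken to log2, and the 75th percentile of the vendor probes of each array was subtracted. Spots of one accession probe were averaged on the log2 scale. Spots marked as outliers by Feature Extraction (316 among the vendor probes) were set to missing. Probes well above background on at least 3 of 6 arrays were tested, after 12 were left out for having under 2 unmarked values in a group, which left 34439. Negative, spike-in and other control spots were left out of the fit. The fit was lmFit and eBayes of limma 3.58.1 in R 4.3.3, shRELA against shCtrl over all 6 arrays with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are shRELA minus shCtrl on the log2 scale. GAPDH and PGK1 end probes were compared with an exact two-sided permutation test.

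The method was tested on simulated data for this comparison: 34439 probes with the observed means and the variances as moderated by eBayes, 200 of them changed. At 3 arrays against 3, 97.5% of probes changed 4-fold were recovered, 66% of those changed 2-fold and 0% of those changed 1.5-fold. At 3 against 2, the shares were 96%, 32% and 0%. The simulated noise was independent between probes, equally wide on all arrays and drawn with moderated variances rather than each probe's own. Few probes changed. In the data, 24.2% of probes had an unadjusted p under 0.05 in limma. The simulated shares therefore need not hold for these arrays.

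The design, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named RELA, the other NF-κB and IκB kinase genes, up to 10 rises and 10 falls among named genes past the threshold with groups that do not overlap, up to 4 called members of each list or, where a list had none, up to 2 members with the lowest p, and 4 reference genes (ACTB, GAPDH, TBP and HPRT1). By this rule GAPDH, PGK1, COX4I1, RPS18, RPLP1 and ACTB were named. Other genes with an accession, RPL10 of the ribosomal protein list among them, are given as well, a choice made after their values were seen. Of the 20 genes, 2 are not reported here and were left out of every fit and count, after the fits had first been run. The vendor probes given by identifier are the 2 largest falls and rises by the same criteria. Planned tests of RELA, of noncoding transcripts and of gene lists could not be made without gene names. A planned choice between several probes of a gene did not apply.

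Alternatives were background correction with normexp (offset 50) on the median signals, since mean signals are not among the columns, quantile and median scaling, other filters, another variance model, array weights, the replicate block, the deposited series table and leaving out each array. Further alternatives were chosen after seeing the data: normexp on the median signals, slide row as a block, row 1 alone, the percentile over probes above background on all arrays, and keeping spots marked as outliers. Slide and scan date as blocks did not apply to 1 slide and 1 scan. Figures were drawn with matplotlib 3.10.9.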

Results

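KG1α, a human acute myeloid leukaemia cell line with an immature myeloid phenotype, was profiled after stable expression of a short hairpin RNA. The hairpin either targeted RELA, which encodes the p65 subunit of the transcription factor NF-κB, or was a control vector. All 6 samples received 0.5 µM daunorubicin, an anthracycline that damages DNA, for 2 h and were collected after the drug was washed out. The comparison asks how gene expression after DNA damage differed between RELA-knockdown cells (shRELA, n = 3) and control cells (shCtrl, n = 3). No array of undamaged cells was analysed here, so a response to the drug itself was not measured. The labels number the samples of each group but do not say whether they were separate cultures, so the p-values measure the spread between these samples, which may be technical.

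Each sample was hybridised to one single-colour array with 58945 vendor probes. A vendor probe carries an identifier without a gene, and only 20 further probes, printed in 10 spots each, carry a transcript accession that leads to a gene; 18 of them are reported here. RELA was not among them, so the knockdown itself was not checked here. The 33 gene lists fixed beforehand (NF-κB targets, DNA repair, p53 targets, apoptosis, cell cycle, interferon response, blood cell markers and others) hold 815 genes, of which 7 are named here. No probe was saturated. The share of vendor probes well above background was 58.7%, 54.5% and 57.3% in shCtrl replicates 1 to 3 and 61.6%, 61.4% and 47.6% in shRELA replicates 1 to 3. The number of arrays limits the precision of every value given here.

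Of the 18 genes reported here by name, none passed the test between shRELA and shCtrl in limma over all 34439 probes tested. None passed either when adjusted over these 18 genes alone. The mean was lower in shRELA for 13 of them and higher for 5, on the scale relative to the 75th percentile of each array. With median scaling the mean was lower for 13 of them and with quantile normalization for 12. Before any scaling it was lower for 0 of them, so the direction depends on whether the arrays are scaled. RPS18 and RPLP1, which encode ribosomal proteins, differed by -0.20 and -0.18 on the log2 scale after scaling. RPL10, which also encodes a ribosomal protein, differed by 0.05, but its probe was dim. It lay at -1.59 in shCtrl and -1.54 in shRELA, against 10.19 and 9.99 for RPS18. The 95th percentile of the negative control probes lay between -2.38 and -1.93, so the RPL10 value says little. GAPDH and PGK1, glycolytic enzymes, differed by -0.19 and -0.17. COX4I1, a subunit of cytochrome c oxidase, differed by -0.17. ACTB, ACTG1 and PFN1, which encode 2 actins and an actin-binding protein, differed by -0.16, -0.09 and -0.16. MTX1, of mitochondrial protein import, and ODC1, of polyamine synthesis, differed by -0.20 and -0.17. RACK1, EIF3D, PRMT1 and ARHGDIA differed by -0.15, 0.05, -0.12 and -0.17. H3-3A, which encodes a histone H3.3, and DYNLL1, a dynein light chain, differed by 0.02 and 0.08. GRM4, a glutamate receptor gene, lay below the 95th percentile of the negative control probes on 5 of the 6 arrays, so its value of 0.29 is one near background; it was 0.0414 with normexp and 0.125 without shRELA replicate 1.

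Of the lists fixed beforehand, 4 held an identifiable gene, and none of these genes passed the test in limma over all probes. None passed either when adjusted over the 18 named genes alone. RPS18, RPLP1, GAPDH, COX4I1 and ACTB were lower on all 3 shRELA arrays than on any shCtrl array, so a small difference is not excluded. Such a separation, in either direction, held for 11 of the 18 named genes, with DYNLL1 the one that was higher, and for 32.5% of all probes tested, against 10% by chance. The ribosomal protein list was measured by 3 of its 35 genes (RPS18, RPLP1 and RPL10), of which RPL10 had a dim probe. The glycolysis list was measured by 2 of 24 (GAPDH and PGK1), and the oxidative phosphorylation list by 1 of 35 (COX4I1). The common reference genes were measured by 3 of 15 reported here (ACTB, GAPDH and PGK1). Their adjusted p from limma ranged upward from 0.2002 for GAPDH. The size of these differences depended on scaling: over the 18 named genes the median was -0.157 on the log2 scale with the 75th percentile and -0.037 with quantile normalization. ACTG1 changed sign, to 0.02, with quantile normalization, and RPL10, to -0.023, with normexp background correction.

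**Figure D1:**
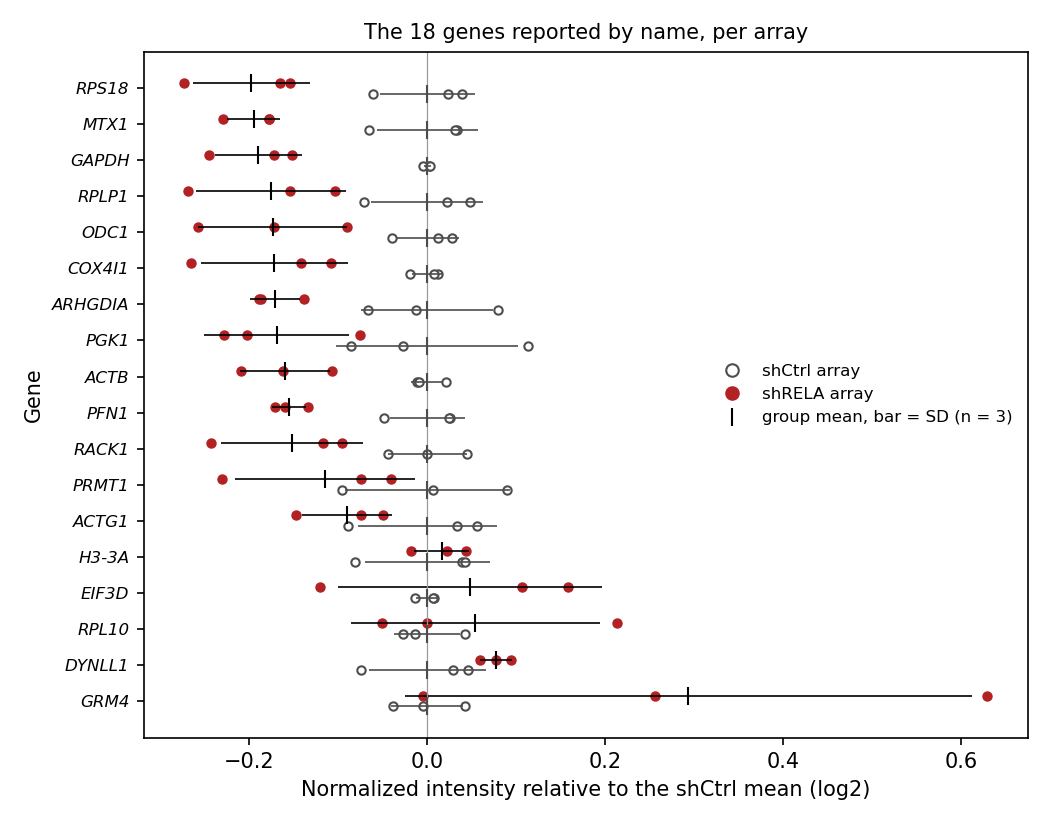
Normalized intensity (log2) of each array relative to the mean of the 3 shCtrl arrays for the 18 genes reported by name; open points are shCtrl arrays, red points shRELA arrays, and the ticks with bars are group means ± SD (n = 3). The mean difference of RPS18 is -0.20; that of GRM4, a probe near background, is 0.29 with all arrays and 0.125 without shRELA replicate 1, and ACTG1 changes sign with quantile normalization and RPL10 with normexp.

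Control probes at both ends of GAPDH and PGK1 were compared between the groups. RNA was labelled by random priming and each end has its own probe, so the size of a gap does not measure RNA integrity. The 3′ probe of GAPDH exceeded the 5′ probe by 1.76 ± 0.17 (SD, n = 3) log2 units in shCtrl and by 1.84 ± 0.07 (SD, n = 3) in shRELA. The same difference for PGK1 was 6.50 ± 0.20 (SD, n = 3) in shCtrl and 6.60 ± 0.09 (SD, n = 3) in shRELA. An exact two-sided permutation test of the group difference gave p = 0.6 for GAPDH and p = 0.7 for PGK1, where the smallest p that 3 arrays against 3 allow is 0.1. The GAPDH probes at the 3′ and 5′ ends differed between the groups by -0.17 and -0.26 (exact permutation p = 0.1 and 0.2), and the PGK1 probes by -0.07 and -0.18 (exact permutation p = 0.4 for both).

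Over all probes, 193 were higher and 147 lower in shRELA at an adjusted p under 0.05 in limma, together 0.99% of the 34439 tested. Of these, 28 were at least 2-fold higher and 33 at least 2-fold lower. The number of called probes depended on processing, from 0, as without a filter on dim probes, to 5258 with array weights. Those weights were 5.23 for shCtrl replicate 1 and 0.526 to 1.154 for the other arrays. The median absolute log2 difference was 0.76 among the 340 called probes and 0.18 among all probes tested. The residual SD within groups, as moderated by eBayes over all probes, had a median of 0.15. An unadjusted p under 0.05 was found for 8331 probes (24.2%), where 1722 are expected by chance. The 3 shRELA arrays lay entirely above or below the 3 shCtrl arrays for 32.5% of probes, against 10% by chance. Whether the called probes belong to coding or noncoding transcripts, or to targets of NF-κB, was not analysed here.

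The called probes sat close to the threshold, and the smallest adjusted p was 0.018. Without any 1 of the 6 arrays no probe passed in limma, and the smallest adjusted p then lay between 0.0691 and 0.177, with 5541 to 8385 probes at an unadjusted p under 0.05. The median absolute log2 difference of the 340 called probes was between 0.726 and 0.8 in these 6 fits, but the probes were chosen with all arrays and their groups do not overlap, so their signs could not change. With the arrays' row on the slide as a block no probe passed in limma either, and 2989 had an unadjusted p under 0.05. The median absolute log2 difference of the 340 called probes was 0.765 in that fit and 0.763 in the main fit. The 340 probes were chosen with all arrays, shCtrl replicate 1 among them, which favours a like size, so this does not test the row. The block's estimate rests on 1 shCtrl array. All 3 shRELA arrays lay in row 1, with 1 shCtrl array, and the other 2 shCtrl arrays in row 2. Within row 1 alone, where the single shCtrl array is assumed to vary like the shRELA arrays, 0 passed in limma, with 4056 at an unadjusted p under 0.05. Row 2 held shCtrl only, so the block and row 1 alone both compare shRELA with shCtrl replicate 1 and are not separate checks.

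Among called vendor probes, the 2 with the largest falls were ASHGA5P001807 and ASHGA5P030559. ASHGA5P001807 went from 2.00 ± 0.42 (SD, n = 3) in shCtrl to -0.49 ± 0.13 (SD, n = 3) in shRELA, a 5.63-fold decrease (limma, adjusted p = 0.0257). ASHGA5P030559 went from 2.75 ± 0.16 (SD, n = 3) to 0.69 ± 0.20 (SD, n = 3), a 4.17-fold decrease (limma, adjusted p = 0.0182). The 2 largest rises were those of ASHGA5P042920, 2.81-fold (limma, adjusted p = 0.0294), and ASHGA5P025237, 2.53-fold (limma, adjusted p = 0.0409). Feature Extraction marked all 4 probes as well above background on all 6 arrays, but on shCtrl replicate 2 ASHGA5P042920 (-2.45) and ASHGA5P025237 (-2.59) lay below the 95th percentile of the negative control probes (-2.04), so the sizes of these rises rest in part on a control level near background. Their genes are not named here.

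**Figure D2:**
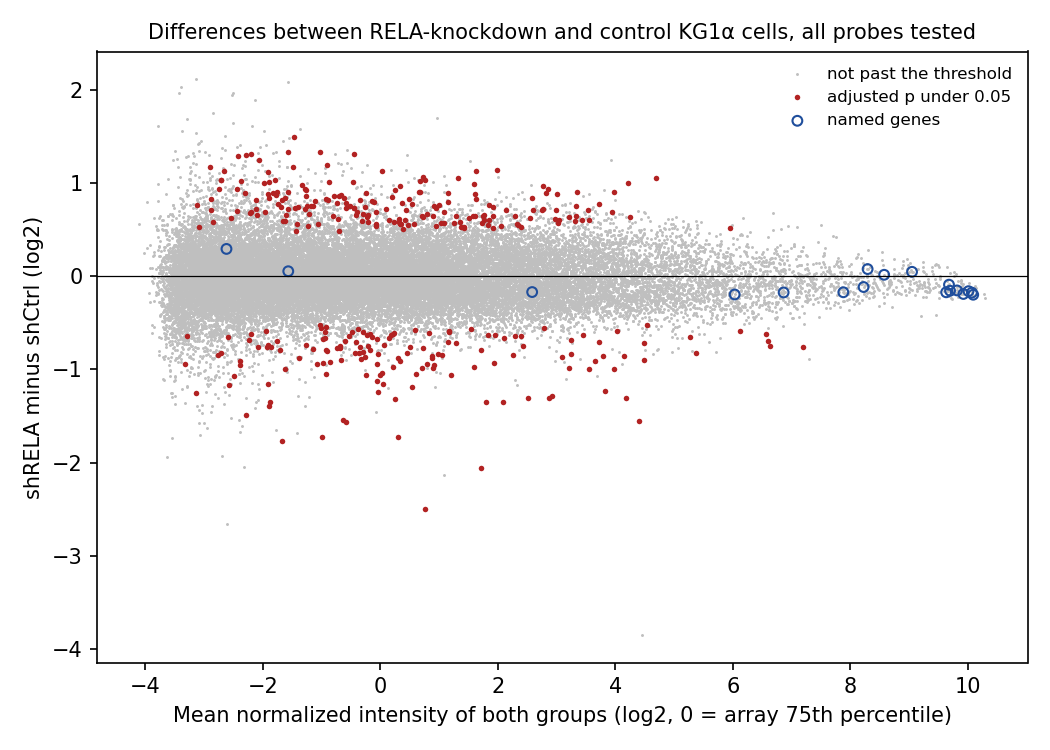
Difference between shRELA and shCtrl (log2, vertical axis) against the mean normalized intensity of both groups (log2, 0 at the 75th percentile of each array) for the 34439 probes tested; red points are the 340 probes at an adjusted p under 0.05 and open circles the 18 named genes. Called probes lie on both sides of 0, 193 above and 147 below, and the 18 named genes are not among them.

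Of the vendor probes, 27402 were well above background on all 6 arrays and 19798 on none. The number well above background on all 3 shRELA arrays and on no shCtrl array was 29, and the number with the opposite pattern was 10. Without shRELA replicate 3, the array with the highest background, these numbers were 873 and 11. This count asks for 2 shRELA arrays rather than 3, and the flags were set on signals before scaling. The 75th percentile intensity was 377.8 and 366.7 on shRELA replicates 1 and 2, against 290 to 301.4 in shCtrl. The number of 873 is therefore not a count of transcripts present in shRELA alone. Of the called probes, 2 were not well above background on any shRELA array, and 0 were not well above background on any shCtrl array.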

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

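Among control probes without a human target, ERCC-00062_278 gave a signal on all 6 arrays above the 95th percentile of the negative control probes, the 1 such probe of 12 ERCC probes. Its mean over the arrays was 1.77 log2 units above the 75th percentile of the vendor probes, with 1.83 ± 0.41 (SD, n = 3) in shCtrl and 1.71 ± 0.08 (SD, n = 3) in shRELA, while the 95th percentile of the negative probes lay between -2.38 and -1.93. None of the 10 E1A spike-in probes (0) rose above that level on all arrays. Whether spike-in RNA was added is not given in the sources used here.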

How the results depend on the processing

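Normexp on the median signals, the slide row, the percentile over probes above background on all arrays and keeping spots marked as outliers were chosen after seeing the data. The counts of called probes depended on most settings. Higher and lower probes numbered 193 and 147, with 61 at least 2-fold. Higher, lower and 2-fold probes were 1629, 1188 and 25 with normexp, 1639, 1171 and 100 with trended robust variances, and 2663, 2595 and 129 with array weights. The weights, estimated gene by gene, were 5.23 for shCtrl replicate 1 and 0.526 to 1.154 for the other arrays. With probes above background on all 6 arrays, 1329 were higher and 875 lower. Quantile normalization gave 391 higher probes and the deposited series values 388, median scaling 97 lower probes, and keeping the outlier spots 90 higher and 90 lower. The cause was not tested. With the percentile over probes above background on all arrays, counts stayed within 1.5 times. In limma all 3 counts were 0 without a filter on dim probes, where 58951 were tested (7237 at an unadjusted p under 0.05). They were also 0 with the slide row as a block (2989). The median absolute log2 difference of the 340 called probes was 0.763 in the main fit and 0.765 with the slide row as a block. In row 1 alone, where 1 shCtrl array was left, it was 0.765 too. These probes were chosen with all arrays. With the replicate block all 3 counts were 0 as well (limma, 7589 at an unadjusted p under 0.05), and that median was 0.761. Deviations of same-numbered arrays correlated at 0.067, 0.059 and 0.012. Replicates 1 and 2 of shCtrl correlated best with their own number, and replicate 3 with shRELA replicate 1. With so few arrays this cannot settle whether equal numbers mark a shared culture or day. Leaving out 1 array in turn gave 0 to 0 probes in each count (limma, 5541 to 8385 at an unadjusted p under 0.05). All 340 called probes had an unadjusted p under 0.05 in each of these 6 fits, but they were chosen with all arrays and their groups do not overlap, so their signs could not change and this does not test their stability. Under the other settings each kept its sign where tested, except 1 probe when outlier spots were kept. With other filters, another variance model, array weights or blocks the signs could not change either. Only other scaling, normexp, the series values and kept outlier spots could change them. Several settings, such as no filter on dim probes or the replicate block, leave the difference of a named gene as it was. The values under alternatives are therefore not separate tests. Of 324 values of named genes under alternatives, 315 kept sign and side of the threshold. The 9 others changed sign, in genes that were not called: RPL10 with normexp (-0.023) and array weights (-0.0088), H3-3A with array weights (-0.0056), the slide row as a block and row 1 alone (-0.023 in both), and ACTG1 with quantile normalization (0.0225). Leaving out 1 array in turn, RPL10 ranged from -0.0257 to 0.1065, H3-3A from -0.0246 to 0.037, EIF3D from -0.007 to 0.132 and GRM4 from 0.1254 to 0.4423. Planned tests of RELA, noncoding transcripts and gene lists (camera and fry), the mean over probes of a gene, normexp on mean signals, and slide or scan date as a block were not run. Signal over background limits dim probes, most in shRELA replicate 3, where the lowest signal well above background was 56.2 against 25.9 to 34.7 on the other arrays.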

Other observations

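The test of other splits was chosen after the results were seen; the tests of slide row and of brightness were written down before their results but after the differences themselves were known.

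The difference between the groups was spread over many probes. Of the 10 splits of the 6 arrays into 3 and 3, 1 split, the real one, gave 340 called probes, and the highest of the others gave 0; 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 in limma the real split gave 8331 probes and the others 554 to 1701. Each other split mixes shRELA and shCtrl arrays, so a group difference widens its residual spread and lowers its counts. All of the others lay below the 1722 expected by chance. They are therefore not a chance reference for the real split. The row of the array on the slide was set against the difference between the groups, since all shRELA arrays and 1 shCtrl array lay in row 1. Over the 500 probes that differed most between shRELA and the row 2 shCtrl arrays, shCtrl replicate 1 lay at a median position of 0.279 (95% of random subsamples of the probes, 0.237 to 0.352), where 0 is the row 2 shCtrl level and 1 the shRELA level. The row 2 arrays, each set against the other shCtrl arrays in the same way, lay at 0.276 and 0.331. Replicate 1 of shCtrl thus lay nearer to the row 2 shCtrl arrays than to shRELA. It is the only shCtrl array of row 1, and its interval is a spread over probes, not arrays. The test therefore cannot settle the part of the row. The row, differences from the construction of the stable lines and the knockdown itself remain open.

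Of the 18 named genes, 13 had lower values in shRELA, with a median of -0.157 on the log2 scale over the 18. Before scaling 0 were lower, with a median of 0.14, and the shRELA arrays were brighter: their 75th percentile intensity was 348.1 to 377.8 against 290 to 301.4 in shCtrl. A candidate explanation is scaling that leaves a brightness-dependent difference, since most of these genes are among the brightest probes and the brightest decile of all probes had a median of -0.061. After subtracting the median of the 200 unnamed probes nearest in brightness, the median of the 18 genes was -0.066. A 95% bootstrap interval over the genes ran from -0.098 to 0.002, a spread over genes, not arrays. RPS18, GAPDH, RPLP1, COX4I1, ACTB, PFN1, RACK1 and ACTG1 had the same reference median (-0.092), so these bright genes were not each matched in brightness. The interval includes 0.5 times the unmatched median (-0.079), so scaling and a lower level of these transcripts cannot be told apart.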
